A study of Mus musculus with 18 samples.

How the data were processed

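RNA sequencing libraries from 18 male C57BL/6J mice were compared, 12 from epididymal white adipose tissue (eWAT) and 6 from liver, 1 library per mouse. Per the submitters' processing notes, ribosomal RNA was depleted, stranded libraries were sequenced in 150-base read pairs on an Illumina HiSeq 4000, adapters were trimmed with cutadapt 1.9.3, reads were aligned with HISAT2 2.0.4, and values per gene came from Cuffdiff and Cufflinks, whose versions are not given. The notes list both mm9 and mm10 as the genome build. The table of each tissue held 22565 genes, of which 83 shared a symbol with another gene and are named here with the Ensembl ID added.

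The authors deposited 2 values per gene and library, an estimated count (expected counts) and an FPKM (fragments per kilobase of transcript and sequencing depth). The deposited expected counts of each library were multiples of 1 factor per library, between 0.78 and 1.236, so that the deposited totals were alike (11432900 to 13360944). Each value was divided by its library's factor and rounded to a whole number, which gave the counts analysed here. Between 94.3% and 95.5% of the low values of a library, up to 20.5 steps, lay within 0.05 of a whole step. The remaining low values were fractional, as estimates for reads shared between transcripts are, so these counts are estimates and not tallies of reads. The deposited FPKM values were used for 2 alternatives only. Gene positions were taken by Ensembl ID from GENCODE vM21, which uses mm10. It holds 21840 of the table's IDs, all on the chromosome the table gives, and 65.8% of them shared a start or an end with the table.

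The recovered totals, here called depth, ran from 9249896 to 16624446 counts per eWAT library and from 11158047 to 15533150 per liver library. Intervals and floors given for single genes cover counting error only. The p-values measure the spread between libraries, and each library is 1 mouse. A group with no counts for a gene was given a floor of 3 counts over the group, and with 1 to 3 counts a ratio was given with its exact (Clopper-Pearson) 95% interval.

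The groups were chow and a high-fat, high-fructose, high-cholesterol diet (HFHC) at 12 and at 28 weeks in eWAT, and saline and recombinant Sparcl1 in liver, with 3 libraries each. The comparisons were HFHC against chow at 12 weeks and at 28 weeks, the difference between these diet effects (the interaction), 28 against 12 weeks within each diet, and Sparcl1 against saline. The titles of the 12-week and of the 28-week libraries carry different prefixes. Time on diet, age and any batch that these prefixes mark therefore coincide, and no fit can part them. Diet was compared within a time point only.

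Genes were kept with edgeR's filterByExpr (14069 of eWAT, 11561 of liver), scaled with TMM factors, and fitted with edgeR's robust quasi-likelihood model, 1 fit over the 12 eWAT libraries (8 residual degrees of freedom) and 1 over the 6 liver libraries (4 residual degrees of freedom). The common biological coefficient of variation was 0.402 in eWAT and 0.19 in liver. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed, over all genes tested in a comparison. Adjusted p-values of genes come from this edgeR test unless another tool is named, and the error of a log2 fold change is its standard error (SE). Values are in CPM, with library totals scaled by the TMM factors, as mean ± SD. For Sparcl1 and Ccl2, the difference in mean log2 CPM was also tested by a two-sided exact permutation test over the 20 arrangements of 3 against 3 libraries, whose smallest p is 0.1.

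Of 43 gene lists fixed with the design, 29 applied to eWAT and 34 to liver. Lists with fewer than 5 tested members were left out, which left 27 in eWAT and 29 in liver. Of the list genes, 482 of 484 were matched for eWAT and 534 of 537 for liver, by symbol or by Ensembl ID. The lists were tested with limma's camera at a preset inter-gene correlation of 0.01 on log2 CPM (prior count 2), adjusted over the lists of a comparison. Camera with an estimated correlation and fry were also run. Fry tests whether the genes of a list move one way on balance and does not compare a list with other genes. Changed members are counted over all genes tested and, separately, adjusted over the list alone. In no called list did the median, the mean and the direction of the test differ in sign. They differed in 24 uncalled results, among them the NF-kB genes in eWAT at 12 weeks (median 0.06, mean −0.01, test downward).

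The genes named in the text were set by a rule. Sparcl1, Ccl2, Ccr2, Tlr4, Adipoq, Lep, Adgre1 (listed as Emr1), Itgax, Col1a1 and Timp1 are given for each diet or treatment comparison, where tested. The 10 largest rises and 10 largest falls past the threshold are taken from genes with a mean of at least 2 CPM and no overlap between the libraries of the 2 groups, without predicted genes (5 and 5 between time points). No overlap has a probability of 10% by chance for 1 gene with 3 against 3 libraries. Of each described list, the 2 to 4 members with the smallest adjusted p are given, and where no gene passes, the 5 smallest. Some genes that this rule names are not reported here. The comparisons, the threshold, the gene lists, this rule and the first group of alternatives given next were set before the data were examined.

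The alternatives set in advance were DESeq2, RLE factors, no filter, a filter at a mean of 1 CPM, limma on log2 FPKM with 1 or 0.1 added, each library left out in turn, the replicate number as a block, a fit of only the groups compared, and for lists the estimated correlation and fry. In eWAT, numbers 7 and 8 occur only in chow 12 weeks, so with the block the mean of that group rested on replicate 4 alone. Number 1 occurs only in chow 28 weeks, whose mean then rested on replicates 3 and 4. Ranges given for lists over their settings include the block, the estimated correlation and fry. Chosen after the data were seen were total-count scaling, limma voom with library weights, a test without genes listed at 0 in 1 library beside at least 10 CPM in the others of its group, and fits without the 2 eWAT libraries that stood apart. Where an alternative leaves 1 group with fewer libraries, the spread is pooled over all groups. Deviations from the group mean were not alike between libraries of the same number in different groups (correlations of −0.12 to 0.182 in eWAT and −0.019 to 0.131 in liver), so the numbers were not treated as pairs.

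The fit was tested on simulated counts with the depths and the gene-wise spread of these libraries and 100 genes changed at each fold. All libraries were drawn with the same spread, so none stood apart as HFHC 28 weeks replicate 4 did. The rates below hold for such libraries only. Of genes changed 4-fold it recovered 55% at 12 weeks, 61% at 28 weeks, 56% between the HFHC groups, 58% between the chow groups and 88% in liver. For a 2-fold change it recovered 5%, 7%, 8%, 7% and 65%. None had the wrong sign, and the false calls were 1, 5, 4, 4 and 18. In each of the comparisons tried for lists, 0 of 20 random lists was called. The simulation carried over the depths and the gene-wise spread, but not the correlation between genes. The random lists therefore cannot decide whether the preset inter-gene correlation is high enough for the real lists. The interaction was not simulated. The tools were R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.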

Results

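Epididymal white adipose tissue (eWAT), a visceral fat pad, and liver of male C57BL/6J mice bought at 6 weeks of age were profiled by RNA sequencing. By its title the study concerns Sparcl1, a secreted glycoprotein of the extracellular matrix in the SPARC family, and CCL2, a chemokine that draws monocytes through its receptor Ccr2. The eWAT came from mice on chow or on a diet of 40% fat, 22% fructose and 2% cholesterol (HFHC) for 12 weeks, which the labels tie to simple fatty liver, or for 28 weeks, which they tie to steatohepatitis. The livers came from mice given saline or 0.2 mg/kg of recombinant Sparcl1 into the abdomen every other day for 3 weeks. The labels do not give the diet of the liver mice. Each of the 6 groups held 3 libraries from 3 mice, and values below are CPM as mean ± SD over these 3. Replicates carry the numbers of the labels. These are 4, 7 and 8 for chow at 12 weeks, 1, 3 and 4 for chow at 28 weeks, 2, 3 and 4 for both HFHC groups, and 1, 2 and 3 for both liver groups.

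Depth at 12 weeks was 14812073, 14755127 and 13710623 counts in the chow libraries and 12136483, 12558896 and 14903962 in the HFHC libraries, in the order of their numbers. At 28 weeks it was 14645102, 15926766 and 14277351 counts on chow and 14981898, 16624446 and 9249896 on HFHC. The liver libraries held 11158047, 11639415 and 11556743 counts with saline and 12619610, 15415185 and 15533150 with Sparcl1. Between 13861 and 17008 genes were detected per eWAT library and between 13652 and 14042 per liver library.

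Both doubtful libraries were in eWAT. HFHC 28 weeks replicate 4 correlated with the other libraries of its group at 0.823 and 0.825, against 0.968 between those, in log2 CPM across genes, which are not independent replicates. It had 21.1% of its counts in mitochondrially encoded genes (2.85% and 3.67% in the others of its group) and 33% in its 10 most abundant genes. By the listed values the higher share came from some of these genes only. Of the 11 tested, 7 lay at least 1 log2 unit lower than in the other pair (median −7.09) and 4 at least 1 higher. Listed at 0 in it were 6 with at least 10 CPM in the others, among them mt-Nd4 (3330 CPM), mt-Nd5 (2240 CPM) and mt-Cytb (5510 CPM). Exactly 0 counts beside such means argue against measured zeros for the genes named, so the median is not read as lower expression. Whether the other zeros were measured is not given. Of the 14069 genes tested, 52.7% lay at least 1 log2 unit from the mean of the other pair, against 5.52% between that pair. Chow 12 weeks replicate 4 held all 12 skeletal muscle markers at their highest value, with a median marker of 1400 CPM against 10.9 to 54.8 CPM in the other 11 eWAT libraries. Both were kept, and counts without them are given with the results they move. The plot of muscle markers and mitochondrial share shows both.

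**Figure D1:**
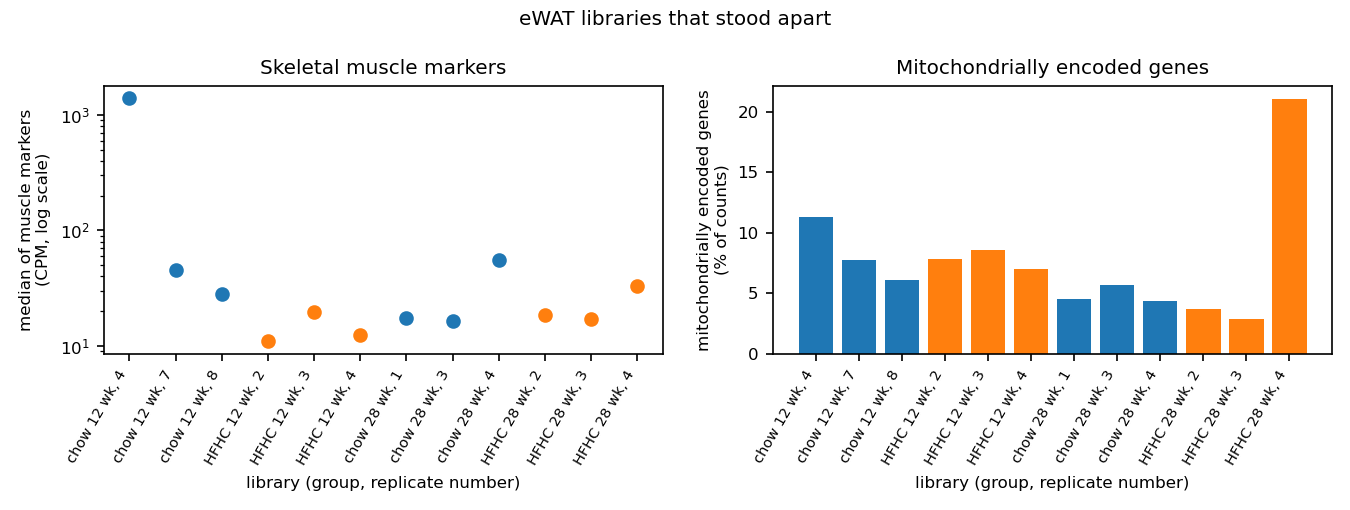
Median CPM of 12 skeletal muscle markers (left, log scale) and percent of counts in mitochondrially encoded genes (right, bars from 0) in each of the 12 eWAT libraries, named by group and replicate number; chow is blue and HFHC orange. Chow 12 weeks replicate 4 stands at 1400 CPM and HFHC 28 weeks replicate 4 at 21.1%. Of the 11 mitochondrially encoded genes tested, 7 were nevertheless listed lower in the latter than in the others of its group. Some mitochondrially encoded genes were listed at 0 in it and may have been left without a value.

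The 12-week comparison asks what HFHC feeding changed in fat before the longer feeding time. Few genes passed the threshold. Among those that rose were Mest and Sfrp5, which are switched on as adipocytes enlarge, and the desaturase gene Scd2. Cyp1a1, a target of the aryl hydrocarbon receptor, fell, as did the kinase gene Sgk1 and the transcription factor gene Tbx3. By camera at its preset correlation, matrix, cholesterol synthesis and cell cycle genes were higher on HFHC as lists and thermogenic genes lower, but none of these lists was called with an estimated correlation (adjusted p = 0.0823, 0.0823, 0.283 and 0.322).

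Of 14069 genes, 17 changed at 12 weeks, 14 higher and 3 lower, and 13 of the 14 and all 3 by at least 2-fold. The largest rise was in Grid1, a glutamate receptor gene (ENSMUSG00000041078, chromosome 14, 34820108 to 35583379), from 0.182 ± 0.107 to 5.44 ± 0.742, a log2 fold change of 4.84 (SE 0.68, adjusted p = 0.0382). Scd2 (ENSMUSG00000025203, chromosome 19, 44293674 to 44306864) went from 94.3 ± 19.2 to 812 ± 401, by 3.11 (SE 0.36). Mest, an imprinted gene that marks fat expansion (chromosome 6, 30723547 to 30748465), went from 142 ± 61.4 to 841 ± 112, and Sfrp5, a Wnt antagonist of adipocytes, from 43.9 ± 11.7 to 225 ± 38.2. Paqr9 (log2 2.76), the tubulin gene Tuba1a (2.60) and Marc1, an outer mitochondrial membrane reductase gene (2.58), rose as well. The other largest rises were those of Ptchd4 (1.98), the collagen-processing gene Pcolce2 (1.68) and Hn1l (1.41), and each of these 10 genes had an adjusted p = 0.0382. The falls were those of Cyp1a1 (8.94 ± 5.21 to 0.3 ± 0.166), Tbx3 (30 ± 4.24 to 11.2 ± 2.25) and Sgk1 (151 ± 30.2 to 61.9 ± 2.4), each with adjusted p = 0.0497. Sparcl1 did not differ, at 479 ± 89.1 against 471 ± 132 (log2 0.02, SE 0.34, adjusted p = 1, exact permutation p = 0.9, two-sided). Ccl2 was at 7.91 ± 3.8 against 2.4 ± 0.353 and did not pass (1.71, SE 0.40, adjusted p = 0.178, exact permutation p = 0.1, the smallest possible). Its HFHC libraries (3.95 to 11.5) each lay above its chow libraries (2.06 to 2.76). Lep, the leptin gene, did not pass either, at 2050 ± 817 against 539 ± 119 (adjusted p = 0.0892). Also not past the threshold were Ccr2 (0.71, adjusted p = 0.857), Tlr4 (0.28, 0.968), Adipoq (−0.11, 1), the macrophage genes Emr1 (0.66, 0.888) and Itgax (0.88, 0.912), Col1a1 (0.30, 1) and Timp1 (1.26, 0.776). The count was 0 without any 1 of chow 12 weeks replicates 4 and 8, HFHC 12 weeks replicates 3 and 4, chow 28 weeks replicates 3 and 4 or HFHC 28 weeks replicates 2 and 3 (658 to 1078 at an unadjusted p under 0.05). It was 3 without chow 28 weeks replicate 1, 6 without HFHC 12 weeks replicate 2, 8 without chow 12 weeks replicate 7 and 201 without HFHC 28 weeks replicate 4, when all 17 kept their call. DESeq2 called 220 genes, and limma on log2 FPKM with 1 added called 10, with 70% of them higher against 82.4%.

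Matrix genes, which build the scaffold around fat cells, were higher on HFHC as a list. None of the 27 extracellular matrix and fibrosis genes passed over all genes and 6 passed when adjusted over the list alone (median log2 0.59, camera adjusted p = 1.42e-07, adjusted p = 0.0823 with an estimated correlation). Col6a3 (1.29, adjusted p = 0.14), Col6a2 (1.48, 0.268) and Fbn1 (1.02, 0.268) came first. Cholesterol synthesis genes were higher (median 0.59, 5 higher and 1 lower of 20 adjusted over the list alone, camera adjusted p = 1.4e-05, adjusted p = 0.0823 with an estimated correlation). The sterol sensor gene Insig1 led them (79.9 ± 9.91 to 247 ± 76.4, adjusted p = 0.0892), before Fdft1 (−0.66, 0.239) and Dhcr7 (1.54, 0.241). All 20 cell cycle genes had a positive log2 fold change (median 0.75, 0 adjusted over the list alone, camera adjusted p = 3.46e-07, adjusted p = 0.283 with an estimated correlation), with Mki67 at 0.97 (0.458) and Top2a at 0.92 (0.465). De novo lipogenesis genes, which make fatty acids from sugar, were higher as a list (1 of 18 rose, 3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0142, adjusted p = 0.539 with an estimated correlation). Scd2 was the gene that rose, with Dgat2 at 1.57 (0.132) and Acacb at −1.29 (0.0525). Lipid-associated macrophage genes were higher (camera adjusted p = 0.0144, adjusted p = 0.459 with an estimated correlation), with Fabp5 at 1.20 (0.352) and Ctsl at 0.62 (0.52). T cell markers were higher (camera adjusted p = 0.00724, adjusted p = 0.539 with an estimated correlation), with Cd8a at 1.63 (0.857). Interferon-stimulated genes were higher (camera adjusted p = 0.032, adjusted p = 0.322 with an estimated correlation), with Gbp2 at 0.76 (0.34) and Ifit3 at 0.59 (0.881). None of these 3 lists had a member that passed, over all genes or adjusted over the list alone. With the replicate number as a block the first 2 turned lower, but chow 12 weeks then rested on replicate 4 alone. Over 9 settings, fry included, the adjusted p of lipid-associated macrophage genes ran from 0.000755 to 0.479. That of T cell markers ran from 1.06e-07 to 0.539.

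Heat-producing genes were lower on HFHC as a list by camera at its preset correlation. The thermogenic adipocyte genes had a median of −1.68 with no member past the threshold (0 of 13 adjusted over the list alone, camera adjusted p = 0.000281, adjusted p = 0.322 with an estimated correlation). Ucp1, the uncoupling protein gene, was at 7.81 ± 1.56 against 40.8 ± 36.2 (adjusted p = 0.456) and Cpt1b at −1.73 (0.48). Oxidative phosphorylation genes (23 of 24 negative, camera adjusted p = 0.0107, adjusted p = 0.647 with an estimated correlation), circadian clock genes (0.0144, 0.283) and mesothelial markers (0.00954, 0.555) were lower as lists, with none past the threshold and none when adjusted over the list alone. Their members with small p-values were Sdha (−0.29, 0.815), Per3 (−0.65, 0.315) and Tef (−0.45, 0.586), and Wt1 (−1.27, 0.731) and Krt18 (−1.93, 0.922). Skeletal muscle markers had a median of −5.34 (12 of 12 lower adjusted over the list alone, camera adjusted p = 1.46e-10, adjusted p = 0.322 with an estimated correlation). Ckm was at 14.6 ± 4.88 on HFHC and 770 ± 1240 on chow (0.216) and Tnni2 at −5.39 (0.216), a contrast that sits mainly in chow 12 weeks replicate 4. Without that library 10 of the 12 called lists kept their call, and de novo lipogenesis (adjusted p = 0.178, range over the 9 settings tried 0.00107 to 0.539) and oxidative phosphorylation genes (0.147, range 1.73e-05 to 0.647) lost it. Macrophage markers (adjusted p = 0.17), chemokines (0.15, 2 of 20 higher adjusted over the list alone), Toll-like receptor 4 pathway genes (0.158) and NF-kB genes (0.655) were not called, with Ccl7 at 2.21 (0.0892) and Lbp, the lipopolysaccharide-binding protein gene, at 1.33 (0.114).

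**Figure D2:**
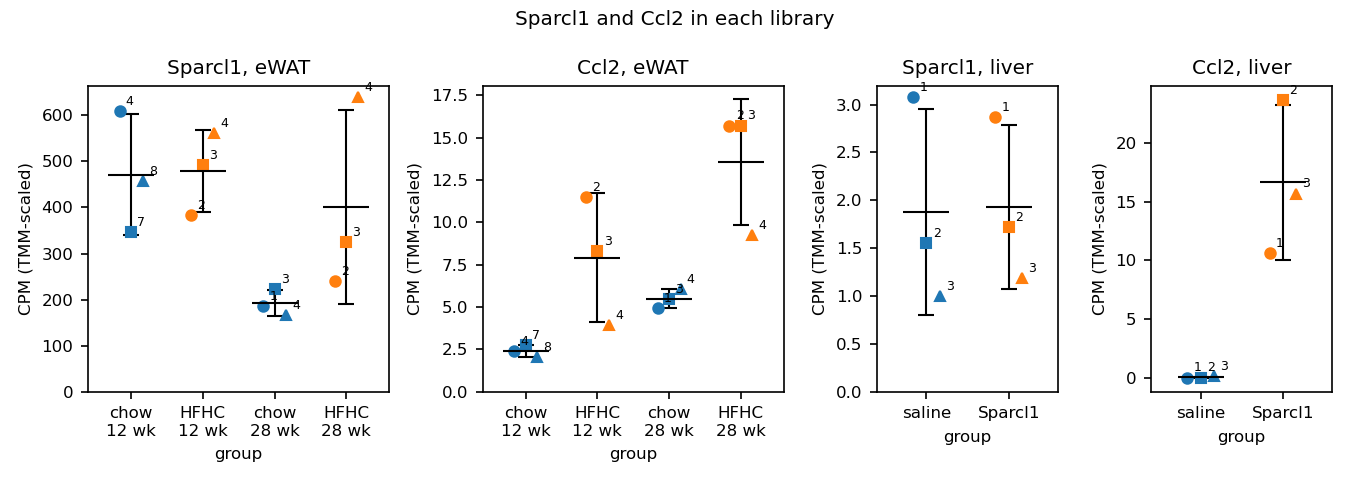
CPM of Sparcl1 and Ccl2 in each eWAT and liver library, with the replicate number beside each point; the horizontal line is the group mean and the bar the SD of 3 libraries. In liver, Ccl2 was at 16.7 ± 6.63 after Sparcl1 and at 0.0304 ± 0.0527 after saline.

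The 28-week comparison asks what HFHC feeding changed in fat by the time the labels tie to steatohepatitis. Several macrophage genes rose, among them genes of lipid-laden macrophages, which gather around dying fat cells and digest their lipid. Some interferon-stimulated (2 of 19), matrix (4 of 27) and cell cycle genes (7 of 20) rose with them, and these lists were called by camera at its preset correlation but not with an estimated one (adjusted p = 0.0876, 0.149 and 0.104). The fat cell genes Cfd and Adrb3 fell, and so did 5 of 16 clock genes, led by Dbp. Lep rose, while Sparcl1 and Ccl2 did not pass the threshold.

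At 28 weeks 366 of 14069 genes changed, 260 higher and 106 lower, 239 and 88 of them by at least 2-fold. The largest rise was in Gpr50, an orphan receptor gene (ENSMUSG00000056380, chromosome X, 71663667 to 71669257), from 0.148 ± 0.152 to 45.8 ± 18.2, by 8.16 log2 units (adjusted p = 0.00739). Tph2, which encodes a serotonin-making enzyme (chromosome 10, 115078641 to 115185022), rose from 1.23 ± 0.485 to 111 ± 53.1 (adjusted p = 0.0112). So did Ubd, an interferon-induced ubiquitin-like gene (chromosome 17, 37193892 to 37196095), from 3.4 ± 1.22 to 160 ± 4.72 (adjusted p = 0.00839). The choline transporter gene Slc5a7 (5.35 ± 4.4 to 266 ± 278), the calcium channel gene Ryr2 (log2 6.65) and Itgad, an integrin of tissue macrophages (5.97), followed. Pex5l (5.27), Arl14epl (5.27), the decoy receptor gene Il13ra2 (5.02) and Car12 (4.73) were the other largest rises. Among the falls, Cfd, the adipsin gene (chromosome 10, 79890853 to 79892655), went from 8760 ± 1630 to 1210 ± 397 (adjusted p = 0.0112) and Dennd2d from 49.2 ± 2.54 to 7.76 ± 0.77 (adjusted p = 0.00739). Pon1 (−5.12), the fatty acid activation gene Acsm3 (44.1 ± 8.26 to 2.25 ± 1.31), Cyp2f2 (−4.21), Smim5 (−3.65), Dok7 (−2.86), Olfr1033 (−2.74), Dcst1 (−2.69) and Acat3 (−2.68) were the other largest falls. Lep rose from 1080 ± 225 to 3710 ± 1380 (1.78, adjusted p = 0.0318). The macrophage gene Emr1 rose from 33 ± 10.8 to 127 ± 53.7 (1.95, adjusted p = 0.0418) and Itgax, which encodes the CD11c surface protein, from 8.15 ± 0.687 to 57.8 ± 34 (2.83, adjusted p = 0.0425). Sparcl1 (ENSMUSG00000029309, chromosome 5, 104079111 to 104113733) was at 401 ± 211 against 192 ± 28.6 (1.06, SE 0.35, adjusted p = 0.128, exact permutation p = 0.1). Its HFHC libraries held 240, 324 and 640, the last in replicate 4, and its chow libraries 167 to 223, and without that replicate its log2 fold change was 0.59 (adjusted p = 0.165, range over 24 alternatives 0.0327 to 0.488). Ccl2 (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453) was at 13.5 ± 3.73 against 5.49 ± 0.577 (1.31, SE 0.39, adjusted p = 0.102, exact permutation p = 0.1). Each HFHC library lay above each chow library in both genes. Ccr2 (1.03, adjusted p = 0.215), Tlr4 (0.71, 0.126), Adipoq (−0.51, 0.272), Col1a1 (1.08, 0.136) and Timp1 (1.07, 0.355) did not pass.

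No gene kept its call at 28 weeks without chow 28 weeks replicate 1 or 4 (1860 and 2131 at an unadjusted p under 0.05), and 27 were called without chow 28 weeks replicate 3. The count was 192 without chow 12 weeks replicate 8, 194, 205 and 222 without HFHC 12 weeks replicates 4, 3 and 2, and 230 without HFHC 28 weeks replicate 2. Without HFHC 28 weeks replicate 4 it was 1066, with 751 higher, and 358 of the 366 kept their call. DESeq2 called 1380 genes.

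Lipid-associated macrophage genes had the largest median (1.92) of the 11 called lists. Of its 19 members 7 rose and none fell, 13 rose when adjusted over the list alone, and the camera adjusted p was 9.53e-10 (adjusted p = 0.0876 with an estimated correlation). Lipa, the lysosomal acid lipase gene (chromosome 19, 34492318 to 34527474), rose from 73.7 ± 7.32 to 283 ± 15.6 (1.94, adjusted p = 0.00739). The proton pump gene Atp6v0d2 rose from 4.46 ± 2.49 to 100 ± 11.2 (adjusted p = 0.0195), the lysosomal protease gene Ctsl from 426 ± 29.5 to 1260 ± 445 (adjusted p = 0.0151) and Slc37a2 from 5.33 ± 1.25 to 50.1 ± 29.7 (adjusted p = 0.0194). Of 20 macrophage markers 7 rose and none fell, 12 when adjusted over the list alone (median 1.07, camera adjusted p = 1.38e-06, adjusted p = 0.195 with an estimated correlation). They were led by Clec4a3 (1.57, adjusted p = 0.0194), Cd68 (57.7 ± 3.39 to 234 ± 71, 0.0219), Ctss (2.09, 0.0251) and Fcgr1 (2.24, 0.0259). In HFHC 28 weeks replicate 4 the median lipid-associated macrophage gene lay 1.09 log2 units and the median macrophage marker 0.57 below the other pair. Without it the adjusted p of these lists was 1e-12 (range over 9 settings 1e-12 to 0.0876) and 2.69e-10 (range 4.21e-11 to 0.195). Without it 16 lists were called, with all 11 below kept.

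Interferon-stimulated genes act against viruses. Of 19, 2 rose and none fell, 10 when adjusted over the list alone (median 1.03, camera adjusted p = 1.57e-06, adjusted p = 0.0876 with an estimated correlation). Rsad2 rose from 3.5 ± 1.56 to 32.7 ± 13.7 (adjusted p = 0.0112) and Ifit1 by 2.40 (0.0463). Of 20 cell cycle genes 7 rose and none fell, 12 when adjusted over the list alone (median 1.51, camera adjusted p = 2.08e-10, adjusted p = 0.104 with an estimated correlation). The proliferation marker gene Mki67 rose from 8.9 ± 1.47 to 43.5 ± 23.9 (adjusted p = 0.0163), Tpx2 by 1.96 (0.0198) and Top2a by 1.62 (0.0364). Of 27 extracellular matrix and fibrosis genes 4 rose and none fell, 7 when adjusted over the list alone (median 0.72, camera adjusted p = 0.000139, adjusted p = 0.149 with an estimated correlation). These were the collagen cross-linker gene Lox (53.3 ± 7.24 to 283 ± 222, adjusted p = 0.0203), Tnc (2.67, 0.0259), Lum (1.62, 0.0292) and Sparc, the relative of Sparcl1 (3100 ± 629 to 7160 ± 732, 0.0329). Cholesterol synthesis genes were higher as a list (1 of 20 rose and 1 fell, 7 and 1 adjusted over the list alone, camera adjusted p = 0.00923, adjusted p = 0.195 with an estimated correlation). Their called members were Insig1, which rose (83.2 ± 15.4 to 305 ± 120, 0.0193), and Fdft1, which fell (−1.08, 0.0163). B cell markers had a median of 1.74 with none of 9 past the threshold, 0 adjusted over the list alone (camera adjusted p = 0.00923, adjusted p = 0.375 with an estimated correlation). Cd79b (2.12, 0.11) and Cd22 (2.74, 0.176) had their smallest p.

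Some clock genes fell. Of 16, 5 fell and none rose, 5 when adjusted over the list alone (median −0.49, camera adjusted p = 0.000456, adjusted p = 0.0876 with an estimated correlation). Dbp (chromosome 7, 45705088 to 45710203) went from 173 ± 27.1 to 36.5 ± 11.6 (adjusted p = 0.00839), Nr1d1, a repressor in the clock, from 269 ± 66.6 to 91.5 ± 9.56 (0.0144). Tef (−1.10, 0.0194) and Per3 (−1.09, 0.0203) followed. Of 22 adipocyte identity genes 2 fell and 1 rose, 5 and 1 adjusted over the list alone (median −0.62, camera adjusted p = 0.00181, adjusted p = 0.375 with an estimated correlation). The falls were Cfd and the adrenergic receptor gene Adrb3 (1460 ± 603 to 294 ± 188, adjusted p = 0.0458), Lep was the rise, and Retn, the resistin gene, came next (−1.37, 0.0548). All 24 oxidative phosphorylation genes were negative with none past the threshold, 0 adjusted over the list alone (median −0.51, camera adjusted p = 2.85e-05, adjusted p = 0.4 with an estimated correlation). Ndufb8 was at −0.80 (0.118). Branched-chain amino acid catabolism genes were lower as a list (0 of 18 past the threshold, 2 lower adjusted over the list alone, camera adjusted p = 0.00136, adjusted p = 0.375 with an estimated correlation). Bckdhb stood at −0.89 (0.0548) and Ivd at −1.31 (0.0702). Chemokines (adjusted p = 0.0815), T cell markers (0.535), NF-kB genes (0.483) and Toll-like receptor 4 pathway genes (0.474) were not called. Even so, Il7r of the T cell list rose by 2.58 (0.0194) and Lbp by 1.57 (210 ± 20.8 to 622 ± 35.4, 0.0195), and Ccl7 stood at 1.20 (0.135).

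**Figure D3:**
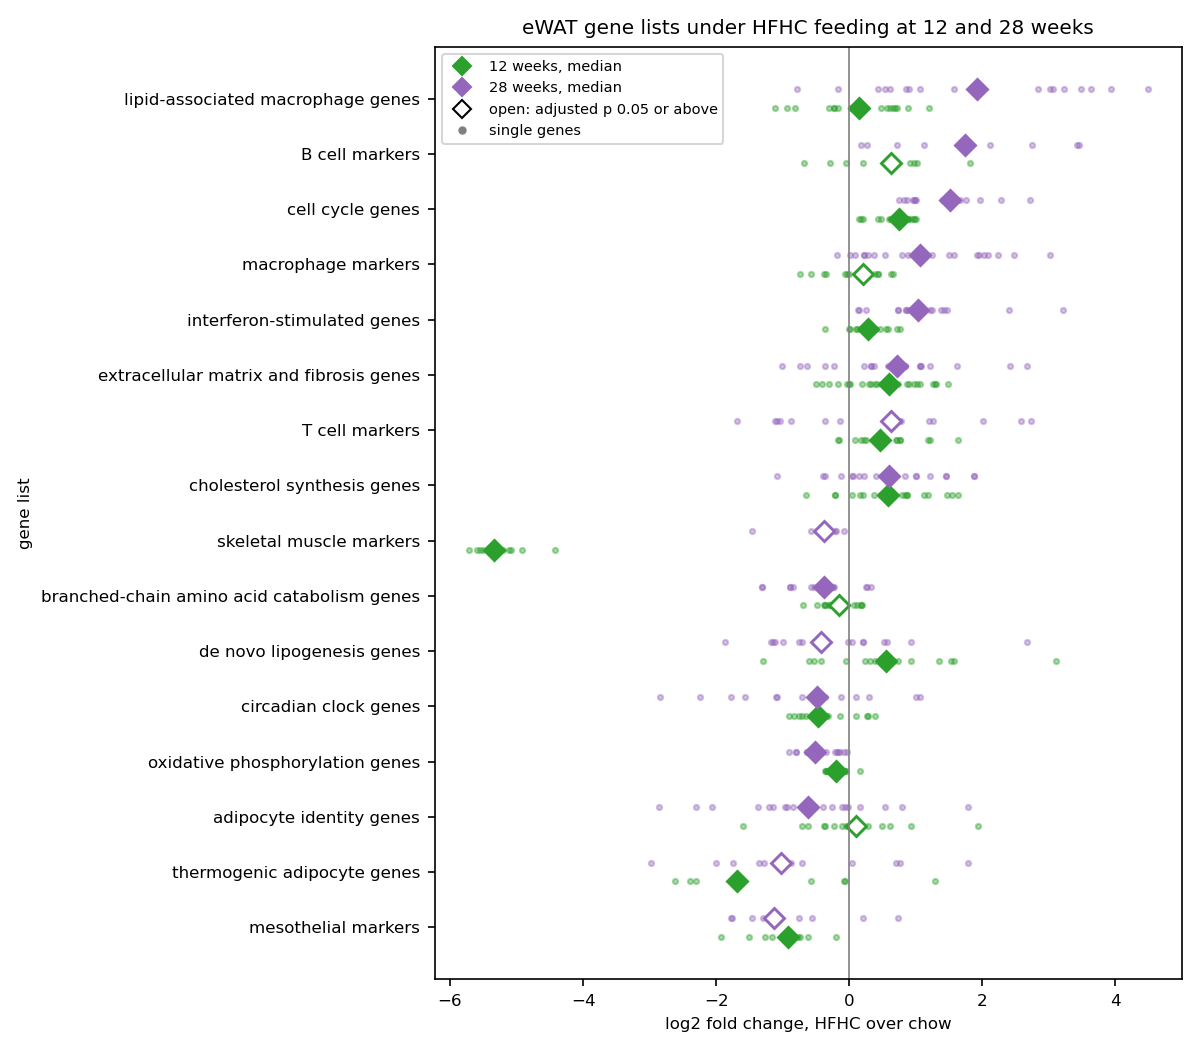
Log2 fold change of HFHC over chow in eWAT for the lists called at 12 weeks (green) or 28 weeks (purple); small points are genes, diamonds are list medians, and open diamonds are lists not called at that time. The median of lipid-associated macrophage genes is 0.15 at 12 weeks and 1.92 at 28 weeks.

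The diet effects at both times shared part of their genes. Of the 14 genes that rose at 12 weeks 8 also rose at 28 weeks: Scd2, Mest, Marc1, Pcolce2, Hn1l, Anxa1, Gtse1 and Dse. If genes were independent, 0.259 would be shared (one-sided Fisher's exact p = 3.33e-11). Both sets of calls come from 1 fit with a shared spread per gene, and genes are not independent, so this p-value does not measure chance. With fits of only the groups compared none was shared, as no gene was called at 12 weeks. None of the 3 genes that fell at 12 weeks was among the 106 that fell at 28 weeks (0.0226 if genes were independent). All 17 genes called at 12 weeks had the same sign at 28 weeks, as had 328 of the 366 called at 28 weeks at 12 weeks (89.6%, against 59.5% of all genes). Without chow 12 weeks replicate 4 no gene was shared, since none was called at 12 weeks, and without HFHC 28 weeks replicate 4 the shared genes were 74 higher and 31 lower.

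Whether the diet acted differently at 28 weeks than at 12 weeks was tested as an interaction. By camera at its preset correlation, macrophage lists had a larger diet effect at the later time and lipogenic and adipocyte lists a lower one, but no single gene passed the threshold. None of these lists was called with an estimated correlation (smallest adjusted p 0.236). The edgeR test called 0 of 14069 genes (1026 at an unadjusted p under 0.05), DESeq2 90 and limma voom with library weights 86, and edgeR called 12 without chow 12 weeks replicate 7 and 7 without HFHC 28 weeks replicate 4. The smallest p-values, none past the threshold, were those of Lipa (1.92), Atp6v0d2 (5.31), Nr1d1 (−1.83), Dbp (−1.93) and Slc6a13 (−1.58), each with adjusted p = 0.486. Sparcl1 had a log2 difference of 1.04 (SE 0.48, adjusted p = 0.683). Of 27 lists 10 differed by camera, 5 upward and 5 downward, and 0 with an estimated correlation or by fry.

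Between 12 and 28 weeks on HFHC macrophage genes were higher as lists at camera's preset correlation, though not with an estimated one, and few other lists were called. Time, age and the prefix of the library titles coincide here. Of 14069 genes 229 changed, 160 higher and 69 lower, which is 69.9% higher against 28.2% with total-count scaling and 38.6% with limma on log2 FPKM with 1 added. Gpr50 rose from 2.87 ± 2.13 to 45.8 ± 18.2 (3.99, adjusted p = 0.0341), the chromatin gene Hmga1 from 5.2 ± 2.04 to 41.1 ± 10.4 (2.99, 0.0113), Tfr2 by 3.08 (0.0465) and Cmtm7 by 2.83 (0.0288). A gene entry under the symbol Rassf8 (ENSMUSG00000045110, with no position in the annotation used) was at 7.41 ± 7.41 at 28 weeks and at 0 in all 3 libraries at 12 weeks, at least 100-fold higher (floor of 3 counts over the group). Acsm3 (−3.59, 0.0365), Olfr1033 (−2.92, 0.0288), Dennd2d (30.9 ± 15.6 to 7.76 ± 0.77, 0.0288), Gng11 (−1.80, 0.0354) and Zfp619 (−1.78, 0.046) fell most. Of 20 macrophage markers 2 rose, 11 adjusted over the list alone (camera adjusted p = 9e-06, adjusted p = 0.702 with an estimated correlation). They were Cd68, from 48.7 ± 4.52 to 234 ± 71 (0.0288), and Ms4a7, from 11.1 ± 0.497 to 31 ± 3.38 (0.0414). Of 19 lipid-associated macrophage genes 2 rose, 12 adjusted over the list alone (camera adjusted p = 6.99e-06, adjusted p = 0.607 with an estimated correlation). They were Lipa, from 107 ± 13.9 to 283 ± 15.6 (0.0288), and Slc37a2, by 2.80 (0.0354). Lower as lists were branched-chain amino acid catabolism genes (median −0.36, camera adjusted p = 0.0106, adjusted p = 0.702 with an estimated correlation) and testis germ cell markers (median −5.97, or −4.68 with 2 genes at their bound, camera adjusted p = 0.0121, adjusted p = 0.884 with an estimated correlation), with none of 18 and 11 past the threshold or adjusted over the list alone. Among the latter, Akap4 was at 1.78 ± 1.86 and at 0 in all 3 libraries at 28 weeks, and Pgk2 at 1.5 ± 1.66 and 0.0216 (0.211). Without HFHC 28 weeks replicate 4 neither was called (0.0979, range over 9 settings 0.00415 to 0.702, and 0.254, range 1.4e-05 to 0.884). Sparcl1 stood at −0.26 (SE 0.34, adjusted p = 0.723, exact permutation p = 0.5). Without HFHC 28 weeks replicate 4 it passed at −0.77 (adjusted p = 0.0271, range over 24 alternatives 0.00539 to 0.994), and it was at 0.01 without HFHC 28 weeks replicate 2. The count was 5729 without HFHC 28 weeks replicate 4, with 3055 higher, and 1 without HFHC 28 weeks replicate 2 or 3. It was 3 to 6 without chow 12 weeks replicate 8, HFHC 12 weeks replicate 2, 3 or 4 or chow 28 weeks replicate 3 or 4, 11 without chow 28 weeks replicate 1 and 104 without chow 12 weeks replicate 4.

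On chow, some adipocyte and lipogenic genes rose with time and 2 cell cycle genes fell. Sparcl1 fell, from 471 ± 132 to 192 ± 28.6 (−1.30, SE 0.35, adjusted p = 0.0447, exact permutation p = 0.1), with each library at 28 weeks below each at 12 weeks. Of 14069 genes 1210 changed, 875 higher and 335 lower, which is 72.3% higher against 39.5% with total-count scaling and 54.6% with limma on log2 FPKM with 1 added. The largest rises were a gene entry under the symbol Mier2 (ENSMUSG00000091854), at 4.99 ± 4.44 and at 0 in all 3 libraries at 12 weeks (at least 73.5-fold higher, adjusted p = 0.0447), and the Rassf8 entry (6.15, 0.0337). Hist2h2aa2 (4.29, 0.0284), Cmtm7 (0.658 ± 0.391 to 8.72 ± 1.37, 0.0095) and Ier5l (3.65, 0.039) came next. The largest falls were muscle genes, Myh1 from 347 ± 567 to 7.42 ± 5.02 (adjusted p = 0.0404), Kcna7 (−5.37, 0.0373), Klhl31 (−4.61, 0.0492) and Rbm24 (−4.58, 0.0447), with Mlf1 (−4.64, 0.0282) beside them. Of 12 skeletal muscle markers 1 fell, 11 adjusted over the list alone (camera adjusted p = 0.017, adjusted p = 0.936 with an estimated correlation). Their adjusted p was 0.383 without chow 12 weeks replicate 4 (range over 9 settings 1.93e-22 to 0.936). Of 22 adipocyte identity genes 7 rose, 10 adjusted over the list alone (camera adjusted p = 0.00353, adjusted p = 0.936 with an estimated correlation). Among them were the lipid droplet gene Cidec (2250 ± 797 to 6750 ± 1320, 0.0222), Gpd1 (299 ± 57.3 to 1020 ± 218, 0.023) and Tusc5 (1.59, 0.0237). Of 18 de novo lipogenesis genes 2 rose, 8 adjusted over the list alone (camera adjusted p = 0.014, adjusted p = 0.936 with an estimated correlation). Srebf1, their master regulator, rose from 64.7 ± 13.3 to 324 ± 41.1 (0.0223) and Dgat2 by 1.85 (0.0216). Mki67 (−1.43, 0.039) and Tpx2 (−1.32, 0.0422) were the 2 of 20 cell cycle genes that fell, 2 adjusted over the list alone (camera adjusted p = 0.0177, adjusted p = 0.936 with an estimated correlation). Gbp3 (−1.04, 0.0337), Rsad2 (−1.82, 0.0365) and Ifit2 (−1.23, 0.0433) were the 3 of 19 interferon-stimulated genes that fell, 5 adjusted over the list alone (camera adjusted p = 0.0412, adjusted p = 0.936 with an estimated correlation). Testis germ cell markers were lower (median −4.91, 0 of 11 adjusted over the list alone, camera adjusted p = 0.0198, adjusted p = 0.936 with an estimated correlation), with Pgk2 at 0.0445 against 3.81 ± 5.58 and Tnp2 at 0.69 ± 1.14 against 18.5 ± 27.8. Without HFHC 28 weeks replicate 4 the adjusted p was 0.0181 for adipocyte identity genes (range over 9 settings 5.42e-06 to 0.936), 0.0956 for de novo lipogenesis genes (5.49e-05 to 0.936) and for cell cycle genes (1e-04 to 0.936), and 0.25 for interferon-stimulated genes (0.0419 to 0.936) and testis germ cell markers (0.0197 to 0.936). The count was 6723 without HFHC 28 weeks replicate 4, with 3383 higher, 2 without chow 12 weeks replicate 4 or chow 28 weeks replicate 1, and 1 without chow 12 weeks replicate 8. It was 33 and 37 without chow 28 weeks replicates 4 and 3, 112, 359 and 447 without HFHC 12 weeks replicates 4, 3 and 2, and 581 without chow 12 weeks replicate 7. Sparcl1 lost its call without each of these 9 chow and HFHC 12-week libraries and chow 28-week libraries.

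The liver comparison asks what injected Sparcl1 changed, and its title gene Ccl2 in the first place. Ccl2 was almost absent after saline and present in each liver after Sparcl1. Some other chemokine, NF-kB and interferon-stimulated genes rose as well. In metabolism, cholesterol synthesis, lipogenesis and protein-folding genes rose in part, and 8 of 21 acute-phase genes, 9 of 20 hepatocyte identity genes and the bile acid gene Cyp7a1 fell. The list calls rest on camera's preset correlation, since none was made with an estimated one (smallest adjusted p 0.537). Macrophage, fibrosis and Toll-like receptor 4 pathway genes were not called as lists.

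Of 11561 liver genes 2393 changed, 1205 higher and 1188 lower, 360 and 410 of them by at least 2-fold. The median fold change of all genes was 0.293 log2 units higher with total-count scaling than with TMM, and the higher share was then 85.4% in place of 50.4%, and 80% with limma on log2 FPKM with 1 added, where the median was 0.211 higher. Ccl2 held 159, 386 and 263 counts in the Sparcl1 livers, which is 10.6, 23.7 and 15.7 CPM, and 0, 0 and 1 count in the saline livers. Its means were 16.7 ± 6.63 and 0.0304 ± 0.0527 (log2 8.65, SE 0.64, adjusted p = 9.27e-05, exact permutation p = 0.1), a ratio of 522 with a 95% counting interval of 93.4 to 2.06e+04. Sparcl1 itself was at 1.93 ± 0.856 against 1.88 ± 1.08 (0.04, SE 0.50, adjusted p = 0.964, exact permutation p = 0.8). Ccr2 (−0.69, adjusted p = 0.655), Tlr4 (0.42, 0.492), Emr1 (0.23, 0.751) and Col1a1 (1.14 ± 1.56 against 9.19 ± 14.4, 0.335) did not pass. After Ccl2, the largest rises were in the heat-shock gene Hspa1a (0.162 ± 0.0573 to 6.89 ± 2.93, adjusted p = 0.000264), the male-specific steroid gene Hsd3b5 (2.42 ± 1.03 to 89.9 ± 26, 0.00018) and the protein-degradation gene Derl3 (4.43, 0.0441). Slc22a28 (3.90, 0.00032), the chemokine gene Cxcl10 (0.701 ± 0.201 to 9.46 ± 4.83, 0.00167), Car3 (3.58, 0.0354) and the guanylate-binding gene Gbp10 (3.45, 0.00017) followed. Mvd of the cholesterol pathway (3.41, 0.0214) rose too. The largest falls were in Igdcc4 (19.9 ± 18.2 to 0.1, −7.46, 0.0289), Fam107a (−4.40, 0.0172), the citrate carrier gene Slc13a5 (−3.54, 0.0199), Slc41a3 (−3.34, 0.00018), Ly6d (−3.20, 0.00539) and Sftpa1 (−3.19, 0.0322). After them came Cyp7a1, which makes bile acids (chromosome 4, 6265612 to 6275633, 206 ± 35.8 to 24.1 ± 7.94, 0.00074), Bmf (−3.07, 0.00739), the atrophy gene Fbxo32 (−3.06, 0.00109) and Fst (−3.05, 0.0181).

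Leaving out a liver library gave 1455 genes without saline replicate 2, 1465 and 1528 without Sparcl1 replicates 2 and 3, and 1888 to 2242 without each of the others. Of the genes above, Ccl2, Hspa1a, Hsd3b5, Slc22a28, Cxcl10, Gbp10, Slc41a3, Ly6d, Cyp7a1, Bmf and Fbxo32 kept their call in all 16 alternatives. Derl3 lost it without any library but saline replicate 1 and Car3 without saline replicate 1 or 3 or Sparcl1 replicate 1 or 3. Mvd and Fam107a lost it without saline or Sparcl1 replicate 2, and Igdcc4 without saline replicate 1 or any 1 Sparcl1 library. Slc13a5 lost it without saline replicate 2 or Sparcl1 replicate 1 or 3, Sftpa1 without any 1 Sparcl1 library, and Fst without saline replicate 2 or Sparcl1 replicate 3.

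Inflammatory genes rose in part. Of 11 chemokines 4 rose and none fell, 5 adjusted over the list alone (median 1.02, the same with Ccl7 at its bound, camera adjusted p = 0.00924, adjusted p = 0.537 with an estimated correlation). They were Ccl2, Cxcl10, Ccl9 (40.1 ± 2.11 to 104 ± 3.5, adjusted p = 7e-05) and Ccl7. The last lies beside Ccl2 (chromosome 11, 82045712 to 82047525) and was at 1.74 ± 1.27 with 84 counts against 0 in all 3 saline livers, at least 18-fold higher (floor of 3 counts over the group, adjusted p = 0.00839). Of 17 NF-kB and inflammatory cytokine genes 4 rose and none fell, 7 and 2 adjusted over the list alone (median 1.23, camera adjusted p = 0.00846, adjusted p = 0.537 with an estimated correlation). Nfkb2 rose by 1.46 (0.00889), Ier3 by 2.59 (0.0211), the adhesion gene Icam1 from 16.5 ± 4.86 to 49.1 ± 17.1 (0.0257) and Relb by 1.23 (0.0367). Of 18 interferon-stimulated genes 5 rose and none fell, 5 adjusted over the list alone (median 0.73, camera adjusted p = 6.27e-05, adjusted p = 0.537 with an estimated correlation). Bst2 rose from 43.8 ± 4.4 to 95.1 ± 9.62 (0.000309) and Isg15 by 1.46 (0.000946). The chemokine and NF-kB lists had an adjusted p of 0.0524 with total-count scaling (ranges over 6 settings 0.0092 to 0.537 and 0.00276 to 0.537). Ier3 lost its call without any 1 saline library, Icam1 without saline replicate 1 or 2 or Sparcl1 replicate 2 or 3, and Relb without any 1 of the 6 libraries.

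Cholesterol synthesis genes, which sterol-sensing SREBP2 drives, had the largest median of the 10 called lists. Of 21, 10 rose and none fell, 20 adjusted over the list alone (median 1.93, camera adjusted p = 6.82e-09, adjusted p = 0.537 with an estimated correlation). Insig1 went from 68.8 ± 16.2 to 262 ± 45 (adjusted p = 0.000297), and Sc5d rose by 0.77 (0.00502). Of 17 de novo lipogenesis genes 9 rose and 1 fell, 10 and 1 adjusted over the list alone (median 0.92, camera adjusted p = 5.38e-05, adjusted p = 0.537 with an estimated correlation). The fatty acid elongase gene Elovl6 (ENSMUSG00000041220, chromosome 3, 129532355 to 129638495) rose from 14.7 ± 2.07 to 105 ± 17.6 (2.84, adjusted p = 1.97e-05), Acly from 70.7 ± 2.66 to 164 ± 27.1 (0.000297), Acaca by 0.98 (0.000548) and Aacs by 2.82 (0.00091).

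Of 20 unfolded protein and integrated stress response genes 11 rose and 2 fell, 13 and 3 adjusted over the list alone (median 0.92, camera adjusted p = 0.00324, adjusted p = 0.537 with an estimated correlation). The chaperone genes Hsp90b1 (830 ± 246 to 3180 ± 500, adjusted p = 0.000546), Hspa5 (721 ± 243 to 2250 ± 347, 0.00245) and Hyou1 (103 ± 35.6 to 447 ± 38.1, 0.00121) rose, and Sesn2 of the amino acid response fell (−1.69, 0.000946). Male-predominant liver genes were higher as a list (6 of 15 rose and 1 fell, 7 and 1 adjusted over the list alone, camera adjusted p = 0.00846, adjusted p = 0.537 with an estimated correlation). Hsd3b5, Slco1a1 (103 ± 8.16 to 320 ± 61, 0.00018) and Cyp7b1 (0.86, 0.00229) rose and Cyp2d9 fell (−0.94, 0.00279). Oxidative phosphorylation genes shifted by a median of 0.14 (1 of 24 rose, 0 adjusted over the list alone, camera adjusted p = 0.0216, adjusted p = 0.818 with an estimated correlation). Ndufs1 rose by 0.40 (0.02), a call lost without saline replicate 1 or 2 or any 1 Sparcl1 library, and Cyc1 was at 0.40 (0.0512). With total-count scaling the adjusted p of the protein-folding and male-predominant lists was 0.0524 (ranges over 6 settings 0.00164 to 0.537 and 0.00367 to 0.537).

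Acute-phase genes, which the liver secretes in inflammation, fell in part. Of 21, 8 fell and none rose, 9 adjusted over the list alone (median −1.39, camera adjusted p = 5.38e-05, adjusted p = 0.579 with an estimated correlation). The list was called in 4 of 6 settings (range 4.12e-09 to 0.579), and lost its call by fry as well as with an estimated correlation. Serpina3n (chromosome 12, 104406729 to 104414329) went from 4340 ± 1380 to 713 ± 279 (adjusted p = 0.00424), Itih3 from 5170 ± 762 to 1680 ± 129 (0.000207). Fga, a fibrinogen gene, went from 20800 ± 6620 to 7930 ± 1630 (0.00595), and Itih4 fell too (−1.21, 0.0031). Of 20 hepatocyte identity genes 9 fell and 1 rose, 10 and 2 adjusted over the list alone (median −0.47, camera adjusted p = 0.00115, adjusted p = 0.537 with an estimated correlation). The smallest p-values were those of Tat (−0.83, 0.00548), Pck1 (−0.77, 0.00663) and Apoa1 (−0.81, 0.0085). Lists that were not called were macrophage markers (1 of 17 rose and 4 fell, adjusted p = 0.158), extracellular matrix and fibrosis genes (3 of 20 fell, 0.498) and Toll-like receptor 4 pathway genes (2 of 20 fell, 0.683). Nor were monocyte-derived macrophage markers (1 of 10 fell, 0.328) and hepatic stellate cell markers (1 of 12 rose, 0.769). With total-count scaling 11 lists were called, 4 higher and 7 lower, in place of 8 and 2, and 6 of the 10 kept their call. The 5 added, all lower, were cell cycle genes, bile acid synthesis and transport genes, cytochrome P450 xenobiotic genes, gluconeogenesis and glycolysis genes and female-predominant liver genes. Of 12 Kupffer cell markers 1 rose and 3 fell (0.331), Nr1h3 upward (0.68, 0.00467) and Cd163 (−1.16, 0.0461) and Folr2 (−0.53, 0.0461) among those downward. Cd163 lost its call without any 1 library but Sparcl1 replicate 1, and Folr2 without any 1 but saline replicate 3.

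**Figure D4:**
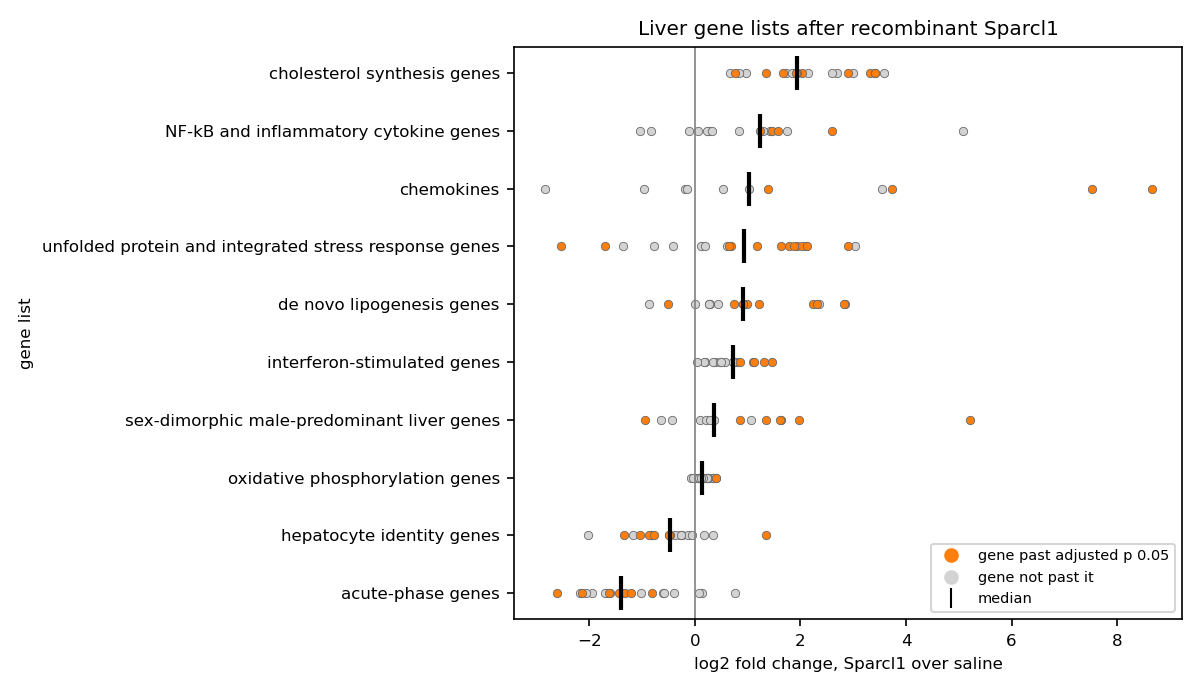
Log2 fold change of Sparcl1 over saline in liver for the 10 called lists; points are genes, orange where past an adjusted p of 0.05, and the black line is the list median. Medians run from −1.39 for acute-phase genes to 1.93 for cholesterol synthesis genes.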

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

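The tests of a swapped label, of muscle as the whole difference, and of both explanations for the muscle markers, and the fits without either doubted library on lists, were chosen after the result was seen. In eWAT, 10 of 27 gene lists responded to the diet differently at 28 than at 12 weeks by the interaction term (camera at a preset correlation of 0.01). By edgeR no single gene passed the threshold (1026 at an unadjusted p under 0.05, with 90 by DESeq2 and 86 by limma voom with library weights), and no list was called with an estimated correlation (smallest adjusted p 0.236) or by fry. These lists therefore rest on the preset correlation.

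Macrophage lists were among those with a larger diet effect at 28 weeks by camera at its preset correlation. With an estimated one the adjusted p was 0.236 for lipid-associated macrophage genes and 0.275 for macrophage markers. Lipid-associated macrophage genes had a median difference of 1.35 (adjusted p = 1.36e-06, 10 of 19 higher adjusted over the list alone), with Lipa at 1.92, Atp6v0d2 at 5.31, Slc37a2 at 3.05 and Spp1, the osteopontin gene, at 4.57, each with adjusted p = 0.486. Macrophage markers had a median of 0.88 (adjusted p = 9.52e-06, 6 of 20 higher adjusted over the list alone), with Fcgr1 at 2.01, Ctss at 1.83 and Mpeg1 at 2.55. Interferon-stimulated genes (median 0.80, adjusted p = 0.000172, 1 higher adjusted over the list alone), led by Rsad2 at 2.75, and cell cycle genes (median 0.72, adjusted p = 4.99e-05, 0 adjusted over the list alone), led by Mki67 at 1.31, were higher as lists at the preset correlation as well. Without HFHC 28 weeks replicate 4, in which macrophage lists were lower than in the others of its group, the adjusted p of macrophage markers was 6.83e-10 (range over 9 settings 6.83e-10 to 0.275).

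Other lists had a negative difference. The median de novo lipogenesis gene shifted between 12 and 28 weeks by 0.68 on chow and by −0.12 on HFHC. For adipocyte identity genes these shifts were 0.89 and 0.08. Time, age and the title prefix coincide, so the difference cannot be assigned to the chow or to the HFHC groups. In HFHC 28 weeks replicate 4 the median genes of these lists lay 0.499 and 0.991 log2 units below the other pair. These chow shifts were not called with an estimated correlation (adjusted p = 0.936 for both), and that of de novo lipogenesis genes was not called without HFHC 28 weeks replicate 4 (0.0956, range over 9 settings 5.49e-05 to 0.936). De novo lipogenesis genes had a median of −0.83 (adjusted p = 0.000101, 0 adjusted over the list alone), with Dgat2 at −1.53, Thrsp at −1.23 and Srebf1 at −1.33, and adipocyte identity genes a median of −0.83 (adjusted p = 4.99e-05, 0 adjusted over the list alone), with Tusc5 at −1.52 and Retn at −1.35. Circadian clock genes (median −0.24, adjusted p = 0.0247, 2 lower adjusted over the list alone), with Nr1d1 at −1.83 and Dbp at −1.93, oxidative phosphorylation genes (median −0.28, adjusted p = 0.0167) and branched-chain amino acid catabolism genes (median −0.35, adjusted p = 0.0167) shifted less, the last 2 with 0 adjusted over the list alone. Oxidative phosphorylation genes lost their call without HFHC 28 weeks replicate 4 (0.231, range over 9 settings 0.00199 to 0.96) and branched-chain amino acid catabolism genes without chow 12 weeks replicate 4 (0.175, range 0.000128 to 0.526). Skeletal muscle markers differed too (median 4.99, adjusted p = 1.84e-05, 11 of 12 higher adjusted over the list alone).

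The muscle markers stand highest in 1 library. In chow 12 weeks replicate 4 all 12 had their highest value, with a median of 1400 CPM, so skeletal muscle taken with the fat pad may explain the excess there. Apart from that library, the other chow 12-week libraries (45.6 and 28.1 CPM) still lay above the HFHC 12-week ones (10.9 to 19.7 CPM), so all 3 chow libraries lay above all 3 HFHC libraries, and a diet effect of a smaller size stays open. Within chow 28 weeks alone the libraries ranged from 16.5 to 54.8 CPM, so a spread of this size also occurs without a difference in diet. Without replicate 4 the difference in skeletal muscle markers at 12 weeks kept its call (2.42e-10, range over 9 settings 1.02e-33 to 0.322), as did the interaction (0.000103). How much muscle was dissected is not given in the sources used here.

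HFHC 28 weeks replicate 4 stood apart from its group. Its lower depth does not explain this: with all libraries thinned to 9249896 counts, the other pair correlated at 0.968 and this library with them at 0.826 and 0.828, a gap of 0.139. A label swapped with another eWAT group stays open. Its median correlation was 0.89 with HFHC 12 weeks and 0.866 with chow 12 weeks, above 0.823 and 0.825 with its own group. With chow 28 weeks it was 0.818. It lay at least 0.0573 below the lowest correlation within each other group, but a library far from every group would do so under any label. Tissue of another kind stays open, as 10 of 12 muscle markers were at least 1 log2 unit higher than in the other pair (median 1.16) and mesothelial markers had a median of 1.69 (6 of 10 higher by 1 unit and 3 lower), but muscle is not the whole difference, since chow 12 weeks replicate 4, with far more of it, correlated with its group at 0.924 or more. The difference rose with gene length at a Spearman rho of 0.232, too little to decide for or against a length bias, and no biological explanation was tested.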

How the results depend on the processing

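Total-count scaling, limma voom with library weights, the fits without the genes listed at 0 beside high values, those without the 2 eWAT libraries that stood apart, and the list and overlap tests under these and without 1 of the 2 libraries were chosen after the result was seen. The cause was not tested for any change below, except that a fit of 2 groups or with a replicate block leaves fewer degrees of freedom. In eWAT the block also leaves chow 12 weeks resting on replicate 4 alone, so block results that use this group are those of 1 control library. It leaves chow 28 weeks resting on replicates 3 and 4.

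Ccl2 in liver kept its direction and its call in all 16 alternatives (log2 fold change 4.55 to 10.8, adjusted p 1.73e-11 to 0.00361). The count of changed liver genes stayed within 1.5 times in 13 of 16, and leaving out 1 library gave 1455 to 2242. In eWAT the count was within 1.5 times in 6 of 24 alternatives at 12 weeks, 7 at 28 weeks, 6 between the HFHC groups, 6 between the chow groups and 18 of 23 for the interaction. At 12 weeks each named gene kept its call in 7 to 14 of the 24, at 28 weeks the largest rises and falls in 7 to 21.

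DESeq2 called 220 genes at 12 weeks, 1380 at 28 weeks, 90 for the interaction, 1373 between the HFHC groups and 3487 between the chow groups. Limma voom with library weights called 403, 2895, 86, 7397 and 6696, and the fit without HFHC 28 weeks replicate 4 and chow 12 weeks replicate 4 called 139, 1285, 2, 6119 and 6117. With the replicate number as a block, edgeR called 0 in each of these 5 eWAT comparisons (550, 1221, 602, 1603 and 876 at an unadjusted p under 0.05), on fewer degrees of freedom. Fits of only the groups compared called 0 at 12 weeks (2033 at an unadjusted p under 0.05), 46 at 28 weeks, 0 between the HFHC groups (1556) and 5835 between the chow groups. Limma on log2 FPKM with 1 added called 10 at 12 weeks, 177 at 28 weeks and 773 between the chow groups, and with 0.1 added 108 at 28 weeks and 659 between the chow groups. Total-count scaling called 215 at 28 weeks and 124 between the HFHC groups, and no filter called 120 between the HFHC groups and 636 between the chow groups. The FPKM scale with 1 added moved the median gene by −0.205 at 28 weeks, −0.213 for the interaction and −0.156 between the HFHC groups.

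Leaving out 1 library gave 0 to 201 genes at 12 weeks, 0 to 1066 at 28 weeks, 0 to 12 for the interaction, 1 to 5729 between the HFHC groups and 1 to 6723 between the chow groups. The highest count came without HFHC 28 weeks replicate 4 in each of these but the interaction, where it came without chow 12 weeks replicate 7.

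Sparcl1 in eWAT at 28 weeks stayed positive in all 24 alternatives (0.51 to 1.32) and passed only with DESeq2 (1.08, adjusted p = 0.0327, range 0.0327 to 0.488). Its fall between the chow groups stayed negative and was called in 14 of 24 (adjusted p 0.00059 to 0.723). It lost its call with the block (−1.49) and without each of 9 libraries, and leaving out 1 library gave −1.46 to −1.09. Between the HFHC groups it passed with voom weights (−0.803), without the 2 libraries (−0.802) and without HFHC 28 weeks replicate 4 (−0.765), and it was at 0.01 without HFHC 28 weeks replicate 2 (adjusted p 0.00539 to 0.994). At 12 weeks it lay between −0.154 without chow 12 weeks replicate 7 and 0.225 without chow 12 weeks replicate 4.

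Signs of uncalled genes also turned. At 12 weeks the replicate block, where chow rested on replicate 4 alone, gave 0.118 for Adipoq, −0.294 for Emr1, −0.0608 for Itgax and −0.4 for Col1a1. Leaving out 1 library gave −0.295 to 0.132 for Adipoq. In liver, voom weights gave −0.138 for Sparcl1, and leaving out 1 library gave −0.353 to 0.603 for Sparcl1, −1.42 to 0.679 for Ccr2, −0.258 to 0.507 for Emr1 and −5.17 to 0.343 for Col1a1.

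With an estimated correlation camera called 0 lists in each of the 6 comparisons: 0 at 12 weeks, 0 at 28 weeks, 0 for the interaction, 0 between the HFHC groups, 0 between the chow groups and 0 in liver. Fry called 2 lists at 12 weeks, 9 at 28 weeks (8 of the 11 kept), 11 in liver (7 of the 10 kept), 0 for the interaction, 0 between the HFHC groups and 0 between the chow groups. The block gave 7 lists at 12 weeks and 16 for the interaction, and without the 2 libraries there were 17 at 28 weeks, 2 between the HFHC groups and 0 between the chow groups. Leaving out either of these libraries gave 2 to 6 lists between the HFHC groups and 1 to 5 between the chow groups. With the block, where chow 12 weeks rested on replicate 4 alone, T cell markers and lipid-associated macrophage genes turned their direction at 12 weeks. Oxidative phosphorylation genes did so for the interaction, and none of these lists was called there. No called list turned with total-count scaling, RLE factors or without the genes listed at 0.

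Genes that rose at both times were 71 with DESeq2, 0 with fits of 2 groups and 0 to 74 without 1 of the 2 libraries, and genes that fell at both were 38 with DESeq2 and 0 to 31 without 1 of them. What depth limits was not tested apart from the spread in eWAT. There, 4-fold changes simulated at these depths and this gene-wise spread, with no library apart, were recovered in 55% to 61% of genes. In liver, 2366 genes were called with each library thinned to 11158047 counts.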

Other observations

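The tests of the time of day and of the scaling, and total-count scaling of the lists, were chosen after the result was seen. Other splits of the libraries were counted for each comparison. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05, and the real split was the only 1 with as many genes in each: 17 genes against at most 0 in the other splits at 12 weeks, 366 against 0 at 28 weeks, 229 against 1 between the HFHC groups, 1210 against 0 between the chow groups and 2393 against 0 in liver. For the interaction edgeR called 0 genes, so that all 100 of 100 splits drawn had as many by construction and decide nothing, and the highest of the others had 7.

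The rise of cholesterol synthesis genes in liver (median 1.93, 10 of 21 called) was tested against 4 other explanations. Scaling, which moves all genes alike, is not one: the list's median lay 1.94 above that of all genes tested by TMM or total-count scaling, and all 21 members lay above the median gene. Depth is not one, as all 10 called members stayed called with each library thinned to 11158047 counts. A different time of day at collection cannot be told apart: 1 of 15 circadian clock genes passed, Per2 (11 ± 1.66 to 30.3 ± 12.3, adjusted p = 0.0227), and Dbp (0.11, SE 1.3) and Nr1d1 (0.11, SE 0.76) varied too much between libraries to exclude a shift. A different time since the last meal stays open: 3 of 4 genes that follow feeding passed in the fed direction, among them Srebf1 (2.31, adjusted p = 0.00793) and Pck1 (−0.77, 0.00663), and Igfbp1 (−1.09, 0.327) did not, so fed Sparcl1 mice may explain part of the lipogenic and sterol changes, or Sparcl1 may act on feeding or on these genes. The design does not part these, and food intake is not given in the sources used here.

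Several liver lists that camera did not call held called genes, some in both directions. Fry, which does not compare a list with other genes, called 4 of them lower: bile acid genes (adjusted p = 0.0419), gluconeogenesis and glycolysis genes (0.0325), female-predominant liver genes (0.0267) and endothelial markers (0.0486). Bile acid genes (4 rose and 6 fell of 19, 4 and 10 adjusted over the list alone, adjusted p = 0.0909) held falls of Cyp7a1 and of Cyp8b1, which sets bile acid composition (471 ± 123 to 90.9 ± 14.2, adjusted p = 0.00015), and rises of the uptake and export genes Slco1a1 and Abcb11 (252 ± 6.44 to 509 ± 30.6, 0.00032). Gluconeogenesis and glycolysis genes (2 rose and 6 fell of 15, adjusted p = 0.0642) held a fall of Ppargc1a (24.4 ± 3.04 to 3.92 ± 1.33, 0.000114). Fatty acid oxidation genes under PPARα (1 rose and 5 fell of 22, adjusted p = 0.331) held falls of Cpt1a (585 ± 81.4 to 178 ± 2.22, 7e-05) and Pdk4 (−1.79, 0.00455) and a rise of Ehhadh (1.15, 0.00336). Cytochrome P450 genes (3 rose and 6 fell of 16, adjusted p = 0.331) held falls of Cyp3a13 (919 ± 15.1 to 285 ± 43.9, 9.58e-05) and of Por, their electron donor (672 ± 76 to 198 ± 45.5, 0.000259). Female-predominant liver genes (0 rose and 3 fell of 7, median −1.65, adjusted p = 0.0603) held falls of Cux2 (−3.72, adjusted p = 0.00299) and Fmo2 (−2.76, 0.0184), opposite to male-predominant genes. Endothelial markers (0 rose and 2 fell of 12, adjusted p = 0.0642) held falls of Erg (5.9 ± 0.425 to 3.34 ± 0.114, 0.0299) and Robo4 (−0.61, 0.0334), calls kept in 7 and 6 of 16 alternatives.

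Some abundant genes were listed at 0 in 1 library beside high values in the others of its group. Scd1, a desaturase gene of fat cells, was listed at 0 in HFHC 12 weeks replicate 4 and HFHC 28 weeks replicate 3, where the others of each group had means of 53500 and 48000 CPM. Alb, the albumin gene, was listed at 0 in Sparcl1 liver replicate 1 beside 47000 CPM. HFHC 28 weeks replicate 4 held 39 such zeros, among them mt-Nd4 (3330 CPM in the others), mt-Nd5 (2240 CPM) and mt-Cytb (5510 CPM). Whether these are measured zeros or genes left without a value is not given in the sources used here. For Scd1, Alb, mt-Nd4, mt-Nd5 and mt-Cytb, exactly 0 counts beside such means argue against measured zeros. The libraries concerned held 14903962, 16624446, 12619610 and 9249896 counts. For the other genes this stays open. The zeros enter the library totals, the mitochondrial share and the lists that hold these genes. In all, 43 eWAT and 2 liver genes had such a zero at 10 CPM or more, and without them 17 genes changed at 12 weeks, 375 at 28 weeks and 2383 in liver.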
